A study of Homo sapiens with 4 samples.

How the data were processed

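HA-tagged PRMT1, a protein arginine methyltransferase, was expressed in primary human keratinocytes from a retroviral vector, and the DNA it was crosslinked to was recovered with antibodies against the HA tag and sequenced (ChIP-seq). Per the labels' protocols, cells were crosslinked with formaldehyde and DSG, a protein-to-protein crosslinker. The 4 libraries form 2 groups by their titles. The control group holds 1 library made with the antibody Ab9110 and 1 made with the antibody C29F4. The D4476 group holds the same pair of antibodies after 60 µM D4476 for 48 hours, a casein kinase 1 inhibitor that the series' design text describes as targeting CSNK1a1. Nothing in the labels says that the libraries of a group came from separate cultures or donors, or which vehicle the control cells received. The spread within a group is therefore a spread between antibodies and may be technical.

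Each library had 1 deposited peak list in BED format with chromosome, start, end, peak name and score. Reads were aligned with Bowtie to the human build hg19 and peaks were called with MACS, per the submitters' processing notes. Versions, parameters, the background library and any filter are not given in the sources used here. The score is the authors' deposited value per peak. No list holds a score under 50, and no header names the scale. It was therefore treated as a score without a known unit and used to describe, rank or filter peaks within a list. Scores were not scaled between libraries, and no read counts, read depths or signal tracks were used here, so the depth of each library is unknown. A peak that is not in a list was not called, and this does not show that the site was unbound. Peak numbers, widths and scores all depend on the sequencing depth and on the calling parameters, which could differ between libraries. Peak names were numbered without a gap in all 4 lists, and no list held overlapping peaks.

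Chromosomes 1 to 22 and X were used. Coordinates are given on hg19, counted from 1. Peaks of all 4 libraries were merged into regions wherever they overlapped by at least 1 bp. A control region was called in both control libraries. It was termed kept if it was called in both D4476 libraries, partly kept if called in 1 of them and lost if called in neither. A region called in both D4476 libraries and in no control library was termed gained. Shares carry Wilson 95% intervals, which cover counting error only. Overlap between lists was compared with 1000 random placements of 1 list within its chromosomes, each taken to end at its last peak, with assembly gaps not excluded. Regions were ranked by their highest peak score as a percentile within each library, averaged over the control or the D4476 libraries. Kept and lost regions were compared by a two-sided permutation test of the difference between median ranks (100000 permutations). Fisher's exact test (two-sided) and exact sign tests were used for counts of regions. Benjamini-Hochberg adjustment was applied to the 5 Fisher tests of region width and not to the sign tests. Neighbouring regions do not vary independently, so these p-values describe the lists and not the biological variation. An exact test of 2 libraries against 2 cannot go below p = 0.33 (two-sided), so no p-value across libraries is given.

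The labels gave no replicate numbers, and the libraries were numbered in accession order only to name them. The antibody ties each control library to a D4476 library, and values within each antibody were computed as an alternative. The other alternatives were a stricter score threshold (the upper 50% of each list, not a common score), lists of equal length and a 50% reciprocal overlap. Peaks of 400 bp, joining peaks within 500 bp and leaving out each library in turn were also run. Circular shifts of the lists, a restriction to regions of 3 kb or less and leaving out each library for the number of peaks were added after seeing the data. The regions named in the text are the 10 with the highest control rank, the 10 highest kept and the 10 highest gained, a rule set before the data were examined. The 10 highest lost regions, the 1 Mb windows, the stretches of neighbouring gained regions and the places among kept regions were chosen after their values were seen, as were the tests of peak width and the order of kept regions. Classification and overlap tests were tested on simulated data. For 15000 simulated, well separated regions with a planted class, the total recovered in each class equalled the total planted. Classes were not compared region by region. Unrelated lists overlapped 0.986 times as often as random placement. Counts of overlapping peaks equalled those of bedtools 2.31.1 (14284 control C29F4 peaks with an Ab9110 peak). The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

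Genomic annotation classes, gene lists and sequence motifs had been planned, but no annotation or sequence of hg19 was used here. Regions are therefore given by position, and the genes they lie in were not analysed here.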

Results

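The data were 4 lists of peaks from ChIP-seq of HA-PRMT1 in undifferentiated primary human keratinocytes, the proliferating cell type of the epidermis. PRMT1 transfers methyl groups to arginine residues of histones and other proteins. The design asked whether D4476, an inhibitor of the kinase CSNK1a1, changes where PRMT1 sits in the genome, and used 2 antibodies against the HA tag as separate readouts. The control lists held 18061 peaks with Ab9110 and 18058 with C29F4. The D4476 lists held 2783 peaks with Ab9110 and 1936 with C29F4. The sequencing depth behind these numbers is unknown.

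In control cells, the antibodies against the tag found largely the same sites. Of the C29F4 peaks, 79.1% (95% interval 78.5 to 79.7) overlapped an Ab9110 peak, and 79.6% (79.1 to 80.2) of the Ab9110 peaks overlapped a C29F4 peak. Random placement of the C29F4 peaks gave 2.16%, and none of 1000 placements reached the observed overlap (one-sided permutation of peak positions, p = 0.001, the smallest these placements can give). These placements scatter peaks over whole chromosomes, and every pair of the 4 lists passed this test, also D4476 with control. The test therefore cannot tell shared PRMT1 sites from enrichment that the libraries share for other reasons. Merging gave 14089 control regions, called with both antibodies. Control peaks had a median width of 1277 bp with Ab9110 and 1373 bp with C29F4, and peaks wider than 5 kb made up 1.19% and 1.32% of the lists.

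The highest-ranked control regions were wide. On chromosome 17, the region from 57913127 to 57925649 (12523 bp) had a score of 3100 with both antibodies, the highest value of either control list, which 2 Ab9110 peaks and 1 C29F4 peak shared. The scores are the authors' and place peaks within a list only. On chromosome 15, the region from 39871182 to 39893799 (22618 bp) scored 3100 with Ab9110 and 2442 with C29F4. The pair on chromosome 11 from 65185775 to 65201644 and from 65263384 to 65277517 scored 2674 and 2373 with Ab9110 and 2708 and 2343 with C29F4. The region on chromosome 12 from 52875749 to 52884488 scored 2691 and 2202, that on chromosome 7 from 5560018 to 5570803 scored 2619 and 2166, and that on chromosome 10 from 3814336 to 3830263 scored 2592 and 1937, with Ab9110 and C29F4 respectively. The 10 highest were completed by chromosome 1 from 153528032 to 153542284 and by 2 neighbours on chromosome 17, from 39734194 to 39745542 and from 39771325 to 39781589.

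The densest 1 Mb windows lay side by side on chromosome 6, with 42 regions between 26 and 27 Mb, 52 between 27 and 28 Mb and 37 between 28 and 29 Mb, against a median of 4 in the 2242 windows with any control region. The window from 39 to 40 Mb on chromosome 17 held 33 regions, and the windows from 73 to 74 Mb on chromosome 17 and from 45 to 46 Mb on chromosome 19 held 32 each.

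After 60 µM D4476 for 48 hours, far fewer sites were called. Peak number fell from 18059.5 ± 2.12 (SD, n = 2 antibodies) to 2359.5 ± 599, a 6.49-fold difference with Ab9110 and a 9.33-fold difference with C29F4. The genome covered by peaks fell from 28.3 to 2.35 Mb with Ab9110 and from 29.8 to 1.47 Mb with C29F4, to 8.31% and 4.92% of control. The gap between the groups exceeded the spread between antibodies, but an exact test of 2 against 2 libraries cannot go below p = 0.33. The remaining D4476 peaks lay mostly at control sites: 89.1% (87.9 to 90.3) of the Ab9110 peaks and 90.6% (89.2 to 91.8) of the C29F4 peaks overlapped a peak of at least 1 control list. The antibodies overlapped less in D4476 cells, where 57.6% (55.4 to 59.8) of the C29F4 peaks had an Ab9110 peak and 0.163% did after random placement (one-sided permutation of peak positions, p = 0.001, the smallest possible). Of the longer D4476 Ab9110 list, 39.1% (37.3 to 40.9) of the peaks had a C29F4 peak. The D4476 lists were shorter and their peaks narrower, which also bears on overlap. With every list cut to its 1936 highest-scoring peaks, 71.4% of C29F4 peaks had an Ab9110 peak in control and 48.2% with D4476. With all peaks cut to 400 bp the shares were 70.6% and 53.3%.

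Of the 14089 control regions, 935 were kept (6.64%, 6.24 to 7.06), 1813 were partly kept (12.9%, 12.3 to 13.4) and 11341 were lost (80.5%, 79.8 to 81.1). Among partly kept regions, the D4476 peak came from Ab9110 in 1219 and from C29F4 in 594. When each antibody was taken alone, 87.5% of the 18057 regions called in control cells with Ab9110 and 91.1% of the 18056 with C29F4 had no D4476 peak of that antibody. Of the 14089 control regions, 84.7% had no Ab9110 peak and 89.2% no C29F4 peak in D4476 cells. The kept count rested on requiring both D4476 libraries: 1528 regions counted as kept without the D4476 Ab9110 library and 2154 without the D4476 C29F4 library. The shares also moved with the length of the lists. Only 1039 regions were called in both D4476 libraries, so no more than these could be kept. The short D4476 lists thus capped the share kept and set a floor under the share lost, and both partly restate the peak numbers. When every list was reduced to its 1936 highest-scoring peaks, 692 of the 1366 control regions were lost (50.7%) and 337 were kept (24.7%).

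Weakly scoring control regions were lost more often than strongly scoring ones. The share kept was 1.10% (0.776 to 1.56) among the 2818 regions of lowest control rank, when all regions were divided into 5 equal groups. It was 1.70%, 2.91% and 7.03% in the next groups and 20.4% (19.0 to 21.97) among the 2818 of highest rank. The median control rank was at percentile 88.1 for kept and 52.1 for lost regions, a difference of 36.0 percentile points (two-sided permutation test, p = 0.00001, the smallest that 100000 permutations can give). The difference was 16.3 points with the upper 50% of each list and 1.76 points with lists of 1936 peaks, which hold strong control peaks only (p = 0.00001 for both, permutation test). Ranks in these shortened lists were those of the full lists, so they span only the upper part of the scale. The sizes of these differences cannot be set against 36.0 points. Although the share kept rose with control rank, 1532 regions of the highest-ranked group were lost (54.4%, 52.5 to 56.2). Of the 21 regions with a control score over 1000 with both antibodies, 13 were kept, 4 were partly kept and 4 were lost.

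**Figure D1:**
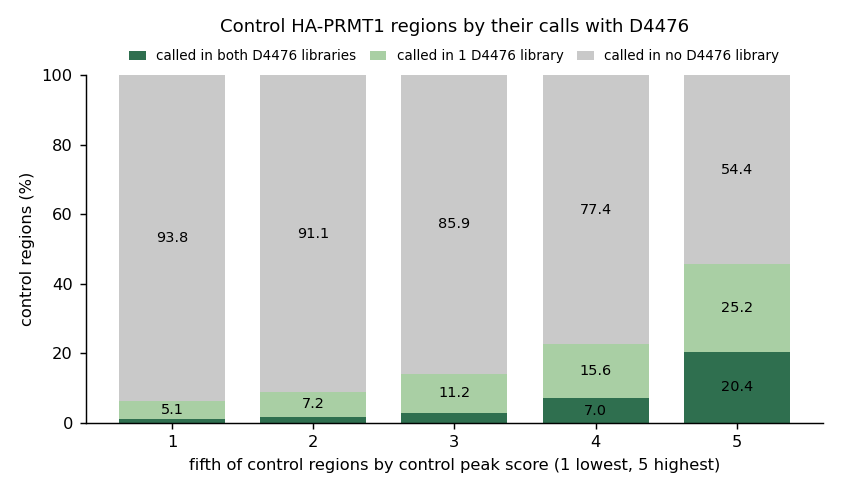
Control HA-PRMT1 regions divided into 5 equal groups by control peak score (x axis, lowest to highest) and the percentage of each group called in both, in 1 or in no D4476 library (y axis). The share kept in both D4476 libraries rises from 1.10% in the lowest group to 20.4% in the highest, where 54.4% are still not called with D4476.

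Lost regions included several of the strongest control sites. The chromosome 15 region from 39871182 to 39893799 and the chromosome 12 region from 52875749 to 52884488, both among the 10 highest in control cells, had no D4476 peak with either antibody. The same held for chromosome 1 from 209600330 to 209610028, with control scores of 2420 and 1582, and for chromosome 6 from 74221177 to 74227385, with 1416 and 1110. Further down the lost list were chromosome 5 from 57743044 to 57757212, chromosome 6 from 26121247 to 26129492, chromosome 5 from 52625992 to 52632127, chromosome 3 from 193851910 to 193860636, chromosome 22 from 36717448 to 36741223 and chromosome 17 from 62222641 to 62226083. Their control scores ranged from 563 to 1227.

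The other 8 of the 10 highest control regions were kept, with unlike standing in the D4476 lists. The chromosome 11 regions from 65185775 to 65201644 and from 65263384 to 65277517 and the chromosome 17 region from 57913127 to 57925649 took the first 3 places of both D4476 libraries among the 935 kept regions. Their D4476 scores were 3227, 2709 and 1327 with Ab9110 and 2248, 1761 and 775 with C29F4. The chromosome 10 region from 3814336 to 3830263 had 679.6 and 492. By contrast, the chromosome 7 region from 5560018 to 5570803 was called with D4476 at 85.5 and 60.5, and the chromosome 1 region from 153528032 to 153542284 at 91.4 and 63.5. The neighbours on chromosome 17 from 39734194 and from 39771325 were called at 92.3 and 134 with Ab9110 and at 68.1 and 59.5 with C29F4. The 10 highest kept regions also included chromosome 21 from 28204211 to 28219494, at 165 and 117, and chromosome 1 from 28831375 to 28846140, at 61.4 and 52.0.

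The order of the kept regions was shared less with the D4476 libraries, and also less between them, than between the control libraries. Among the 935 regions, Spearman's rho between control and D4476 scores was 0.39 with Ab9110, 0.29 with C29F4, 0.38 between control C29F4 and D4476 Ab9110 and 0.25 between control Ab9110 and D4476 C29F4, against 0.85 between the control libraries and 0.41 between the D4476 libraries. These are correlations across regions, which are not independent replicates, and with 0.41 between the D4476 libraries a difference between the groups cannot be read from them. In each library, 46 regions made up the highest 5%. Of these, 36 were shared by both control libraries and 31 by both D4476 libraries, and 11 were shared by all 4.

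**Figure D2:**
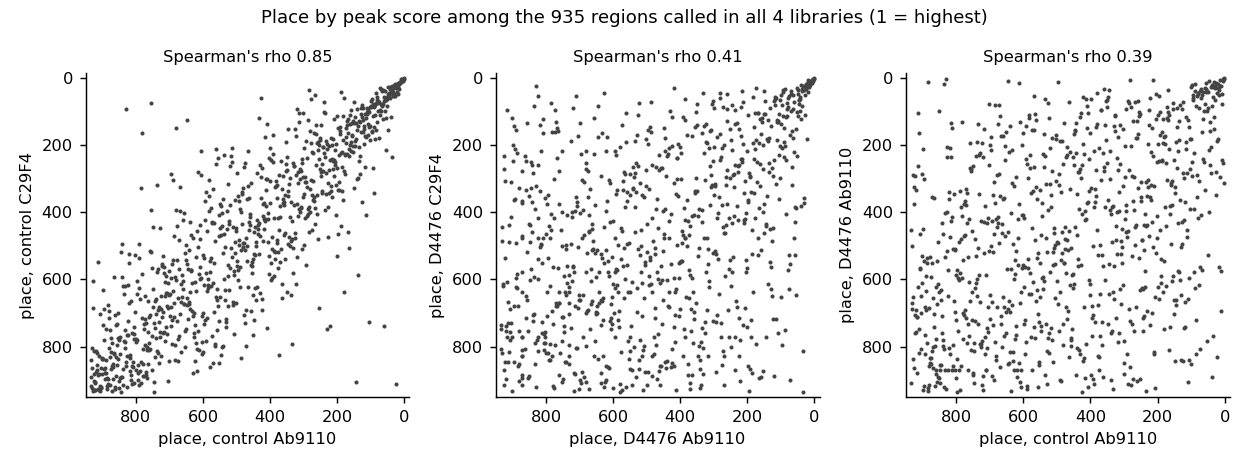
Place by peak score (1 is the highest) of the 935 regions called in all 4 libraries, each point 1 region, for the control libraries (left), the D4476 libraries (middle) and control against D4476 with Ab9110 (right). The control libraries order the regions alike (rho 0.85), while the D4476 libraries (0.41) and the control against D4476 (0.39) scatter widely.

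Peaks were narrower with D4476. The median width was 697 bp with Ab9110 and 632 bp with C29F4, against 1277 and 1373 bp in control. In the same 935 kept regions, the called length was smaller with D4476 in 928 with Ab9110 and in 929 with C29F4 (exact sign tests, p = 8.41e-265 and 6.33e-267), with median ratios of 0.52 and 0.45. Each sign test set 1 D4476 library against 1 control library. A difference between whole libraries would narrow all regions together, so these p-values describe the lists and not an effect of D4476. Of the D4476 peaks that overlapped a control peak of the same antibody, 94.9% and 96.5% lay wholly inside it. Scores of different lists have no known common scale. At scores from 50 to 60 in their own list, median widths were 642 and 567 bp with D4476 and 1043 and 1117 bp in control. At scores from 150 to 300 the D4476 to control ratio was 0.956 with Ab9110 and 0.872 with C29F4. At scores of 300 and over, where the D4476 lists held 34 and 24 peaks, they were 4117 and 3178 bp against 3750 and 4063 bp.

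**Figure D3:**
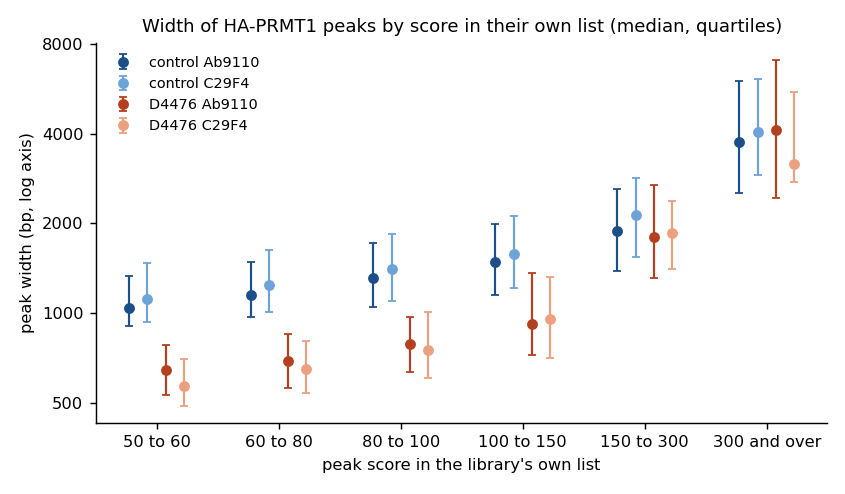
Peak width (y axis, bp, log axis) against the score in the library's own list (x axis) for the 4 libraries; points are medians and bars span the quartiles. Below a score of 150 the medians of both D4476 libraries lie under those of both control libraries (642 and 567 bp against 1043 and 1117 bp at scores from 50 to 60), and from 100 upwards the quartile ranges of control and D4476 overlap with each antibody.

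Region width went with the loss in unlike ways over all control regions and at a given control rank. Over all control regions, the median width was 1599 bp for kept and 1558 bp for lost regions. The share kept was 5.98% among the 12712 regions of 3 kb or less, against 6.64% of all 14089, so regions over 3 kb were kept more often. This difference was not tested. In each of the 5 groups of control rank, regions narrower than the group's median were kept more often than wider ones. The shares were 1.91% and 0.284% in the lowest group, 10.7% and 3.34% in the next to highest and 23.1% and 17.8% in the highest. All 5 differences passed Fisher's exact test with Benjamini-Hochberg adjustment (adjusted p from 4.06e-14 to 0.000647).

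When all peaks were used, fewer sites appeared only after D4476 than were kept. Of the 1039 regions called with both antibodies in D4476 cells, 935 were the kept regions, 53 (5.10%, 3.92 to 6.61) had a peak in 1 control library and 51 (4.91%, 3.75 to 6.40) were gained. The gained region of highest rank lay on chromosome 15 from 41246928 to 41251237 (4310 bp), with scores of 579.7 and 393 with Ab9110 and C29F4. It was followed by chromosome 1 from 209804944 to 209812335, at 357 and 249, chromosome 5 from 137803449 to 137806389, at 296 and 186, chromosome 12 from 57909293 to 57911555, at 167 and 128, and chromosome 8 from 6506082 to 6507325, at 94.3 and 128. The chromosome 1 region at 145014200 to 145016472 scored 110 and 80.6. In 28 of the 51 gained regions both scores were under 80. With lists of equal length 391 regions were gained and 337 kept. Shortening took called peaks out of the control lists, so a region gained there may have a control peak in the full lists. With a 50% reciprocal overlap 438 were gained and 300 kept. A D4476 peak less than 50% as wide as the control peak around it cannot meet that rule. Without the D4476 Ab9110 library the gained count was 182, without the D4476 C29F4 library 302, without the control Ab9110 library 89 and without the control C29F4 library 83.

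The remaining 4 of the 10 highest gained regions lay beside the second one on chromosome 1. Between 209784910 and 209820400, 6 gained regions followed each other within 35491 bp. Both control libraries had called peaks on each side of this stretch, 17 with Ab9110 and 18 with C29F4 within 200 kb, and none inside it. Another 3 gained regions lay on chromosome 5 between 179252257 and 179260583. In all, 9 of the 51 gained regions lay within 50 kb of another gained region, and all 9 lay in these stretches.

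**Figure D4:**
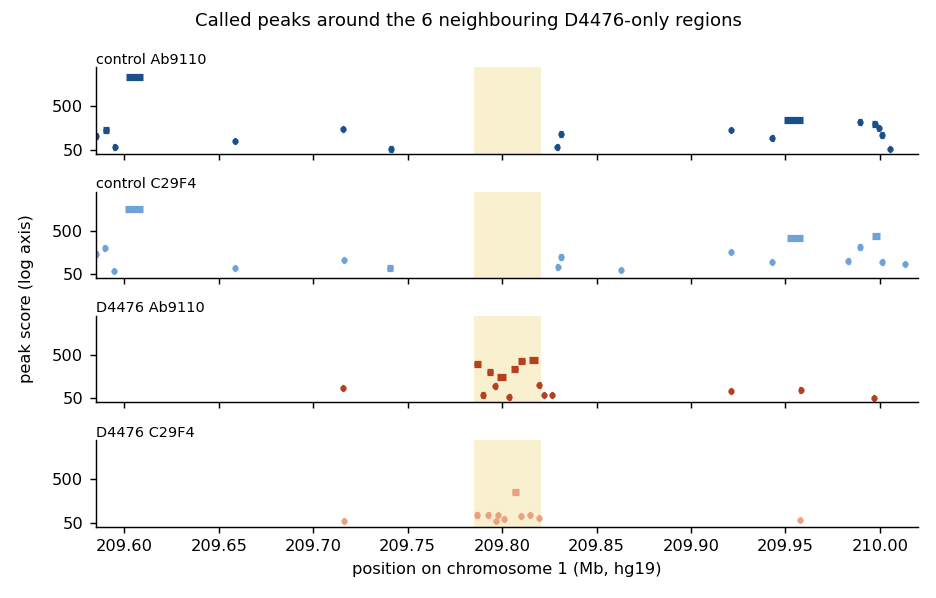
Called peaks on chromosome 1 (x axis, Mb on hg19) in the 4 libraries, each drawn as a line as wide as the peak, with a dot at its centre, at its score (y axis, log axis), within 200 kb of the stretch from 209784910 to 209820400 (shaded). The shaded stretch holds 10 peaks with Ab9110 and 9 with C29F4 in D4476 cells and none in control cells, whereas the control region starting at 209600330 has no D4476 peak.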

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

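The circular shifts, the restriction to regions of 3 kb or less, and leaving out libraries for the number of peaks were chosen only after the results were seen. Under every alternative run for them, 3 results kept their direction and, where tested, their side of the threshold. D4476 peaks as a percentage of control peaks (13.1%) ranged from 10.7% to 15.4%. Taking the upper 50% of each list fixes this percentage by construction, and leaving out libraries only recombines the same counts. The percentage was therefore not tested at a stricter common score. The overlap of C29F4 with Ab9110 peaks ranged from 70.6% to 79.7% in control and from 48.2% to 58.2% with D4476. The difference in control rank between kept and lost regions (36.0) ranged from 1.76 to 44.1 percentile points. Its lowest values, 1.76 and 16.3, came from shortened lists that span only the upper part of the rank scale. The number of kept regions (935) was 2251 within Ab9110 and 1611 within C29F4 (antibody pairs as a replicate block), 337 with lists of equal length, 300 with a 50% reciprocal overlap, 403 with the upper 50% of each list, and 958 to 2154 when 1 library was left out. The number of gained regions (51) was 415 and 273 within the antibodies, 391 with lists of equal length, 438 with a 50% reciprocal overlap, 156 with peaks of 400 bp, and 83 to 302 when 1 library was left out. The share of control regions lost (80.5%) was 87.5% and 91.1% within the antibodies, of 18057 and 18056 regions called with that antibody in control, 50.7% with lists of equal length, 89.8% with a 50% reciprocal overlap, 81.7% with peaks of 400 bp, 81.4% in regions of 3 kb or less, 81.5% with the upper 50% of each list, and 83.8% to 89.2% when 1 library was left out. By construction, requiring 1 library in place of both raises the counts, and shorter lists lower the number of kept regions. Lists of equal length also drop called control peaks. A 50% reciprocal overlap cannot be met by a D4476 peak less than 50% as wide as its control peak. With peaks of 400 bp, a D4476 peak away from the midpoint of its control peak may no longer overlap it. Lists of equal length, a 50% reciprocal overlap and peaks of 400 bp can therefore each count as gained a region with a control peak in the full lists. For the other moves the cause was not tested. The overlap between antibodies needs both libraries, so none could be left out there. The alternatives for genomic annotation, gene lists, sequence motifs, repeat-masked regions and assembly gaps were not run. Reads per library are unknown, so the part of the loss that goes with depth cannot be given, and a lost region is one under the calling threshold.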

Other observations

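The places among kept regions, the 1 Mb windows and all tests of explanations in this part were chosen only after the result was seen. Some kept regions took high places with D4476 and lower places among the kept regions in control cells. Among the 935 kept regions, 3 were in the highest 5% of both D4476 libraries and below the middle place of both control libraries. They lay on chromosome 5 from 172191698 to 172200281 (8584 bp; places 11 and 13 with D4476, 884 and 911 in control), on chromosome 19 from 49466738 to 49472163 (places 17 and 17, against 836 and 783) and on chromosome X from 23802224 to 23806277 (places 15 and 25, against 614 and 502). Among all peaks of the control lists their mean ranks were at percentile 31.0, 58.5 and 84.0, in that order, so the last was not low in control cells. The reverse held for 2 regions, chromosome 1 from 28831375 to 28846140 (places 10 and 10 in control, 693 and 874 with D4476) and chromosome 2 from 113529300 to 113534103 (places 11 and 11, against 576 and 816). The 31 regions in the highest 5% of both D4476 libraries had a median width of 7745 bp, against 6674.5 bp for the 36 in the highest 5% of both control libraries and 1599 bp for all kept regions. On chromosome 15, the adjoining regions from 60630663 to 60642152 and from 60642304 to 60658114 took places 5 and 4 with D4476 and 14 and 830 in control with Ab9110, and places 9 and 4 with D4476 and 13 and 93 in control with C29F4.

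In the 8 densest 1 Mb windows of control regions the share lost ranged from 56.8% to 93.8%, and differences between them were not tested. In the window from 73 to 74 Mb on chromosome 17, 30 of 32 control regions were lost (93.8%) and 0 were kept. In the windows on chromosome 6 from 26 to 27, 27 to 28 and 28 to 29 Mb the share lost was 66.7%, 69.2% and 56.8%, against 80.5% of all control regions. In the other 4 it was 72.7% (chromosome 17, 39 to 40 Mb), 81.3% (chromosome 19, 45 to 46 Mb), 83.9% (chromosome 11, 64 to 65 Mb) and 87.1% (chromosome 1, 151 to 152 Mb). In D4476 cells the densest window was that from 209 to 210 Mb on chromosome 1, with 8 regions, 6 of them gained.

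The loss of called regions with D4476 is the pattern a reader would first follow up. Failure of 1 antibody is excluded, because the smaller of the folds in peak number was 6.49. A uniform loss of signal, from fewer reads, a lower yield or a stricter threshold, may be part of the cause. The kept share rose to 20.4% in the highest-ranked group, which such a loss would give. Any loss that moves peaks towards the calling threshold, also an effect of D4476 on PRMT1 binding, would give this rise too. The rise therefore cannot tell them apart. As the whole cause, a uniform loss of signal is argued against only where it leaves the score order of the control peaks unchanged. Of the D4476 C29F4 peaks, 41.1% (38.9 to 43.3) lay in the 2783 strongest control Ab9110 peaks. In the equally long D4476 Ab9110 list it was 57.6% (55.4 to 59.8). The reverse pairing gave 31.9% (30.2 to 33.6) against 39.1% (37.3 to 40.9). Noise shared by the D4476 libraries, if they came from 1 chromatin sample or were called against 1 background library, stays open and untested. A fragment length, read extension or calling setting common to the D4476 libraries could reorder the peaks and also stays open. The same holds for an effect of D4476 on PRMT1 binding itself.

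The narrower D4476 peaks form the next pattern. At scores from 50 to 150 the D4476 to control ratio of median width was at most 0.617 with either antibody, and at 150 to 300 it was 0.956 and 0.872, but the scores of different lists have no known common scale, so lower scores stay open as an explanation. The narrowest peaks differed too: the 1st percentile of width was 357 bp smaller with D4476 for Ab9110 and 392 bp smaller for C29F4. A shorter fragment length or read extension in the D4476 libraries could give this, and it cannot be told apart from narrower binding, since fragment lengths and calling parameters are unknown. The hypothesis of narrower binding was not tested.

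The regions called only with D4476 are the last pattern. The 6 neighbours on chromosome 1 cover 75.2% of their span, with gaps of 39 to 3466 bp, so they may be 1 broad enriched stretch called in pieces; counted by stretch, the 51 gained regions make up 44 loci. A control signal just under the threshold was tested by the share of gained regions among D4476 regions with both scores over 100, which was 4.94% (4 of 81, 1.94 to 12.02), against 4.91% (3.71 to 6.46) among the others. With 81 strong regions this leaves the explanation open. A local response to D4476 stays open as well.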
